A study of Arabidopsis thaliana with 27 samples.

How the data were processed

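Total RNA from the aerial parts of Arabidopsis thaliana Col-0 was measured on 27 Agilent arrays of 1 colour (Cy3), 1 per plant sample, with 3 arrays in each of 9 groups. Per the labels, plants grown in soil for 2 weeks were left untreated, or received water or 10 mM acetic acid for 9 days and then no water for 0, 6, 9 or 12 days. These are called untreated plants, water plants and acid plants, and the days without water are called day 0, 6, 9 and 12. Groups and replicate numbers were taken from the sample labels, and the series description states that replicates are independent biological samples.

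The deposited scanner files hold fluorescence intensity for 45220 spots per array, made by the authors with Feature Extraction 9.1.3.1, per the file headers. Its processed intensity is background-subtracted and detrended within each array, per the file headers, and the deposited values show no scaling between arrays. The mean and local background intensity of each spot and its marks (well above background, saturated, outlier) were also deposited. The deposited series matrix gives 1 value for each of 43661 probes and array. On every array these values equalled log2 of the processed intensity minus a constant, with an SD over probes of at most 3.49e-07, and the constant lay within 0.0124 of that array's 75th percentile. The deposited log2 scale, direction and centring per array therefore followed from the values, and how the authors chose the constant is not stated. Medians of the deposited log2 columns were -2.67, -2.63 and -2.63 (untreated), -2.70, -2.80 and -2.68 (water, day 0), -2.70, -2.72 and -2.71 (water, day 6), -2.80, -2.73 and -2.78 (water, day 9), -3.33, -3.38 and -3.33 (water, day 12), -2.69, -2.65 and -2.63 (acid, day 0), -2.81, -2.75 and -2.72 (acid, day 6), -2.87, -2.83 and -2.80 (acid, day 9), -3.1, -3.15 and -3.19 (acid, day 12).

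Log2 of the processed intensity minus the array's 75th percentile over 43603 probes outside the 1417 control spots was used, with spots of a probe averaged and outlier spots left out. A locus in the probe annotation belonged to 38413 probes, for 29030 loci, and 5190 probes without one were not used. Symbols came from a reference table of assembly TAIR10.1, which matched 28595 loci and gave 10667 a symbol; the files name no genome build, so no coordinates are given. A probe entered the tests if it was well above background on all 3 arrays of at least 1 group and had at least 2 arrays without an outlier mark in every group. This held for 21535 genes (9253 with a symbol), each represented by its brightest such probe, and 360 of 32559 detected probes were lost to outlier marks. Where several probes of a gene were called, directions opposed for 1 of 384 genes in acid against water plants at day 0 and for up to 203 of 3749 at day 12. Among genes eligible for naming, the probes opposed for P5CDH (AT5G62530) in acid against water plants at day 9, for GSTF12 (AT5G17220) in water plants at day 12 against day 0 and against untreated plants at day 0, and for RAB18 (AT5G66400) in acid plants at day 9 against day 0.

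Linear models were fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8, jsonlite 2.0.0; plots with matplotlib 3.10.9 in Python 3.11.15), with 1 mean per group, all 27 arrays sharing 1 spread per gene (18 residual degrees of freedom), and eBayes with a trend. The 14 comparisons were acid against water plants on each of the 4 days, days 6, 9 and 12 against day 0 within water and within acid plants, the difference between those drought responses (acid by drought interaction), and water plants at day 0 against untreated plants. P values were adjusted with Benjamini-Hochberg over the genes of a comparison, and a gene was called at an adjusted p below 0.05. Replicate and slide were no terms of the model. A gene not well above background on any array of 1 group has only a bound there, so its fold is given as "at least N-fold": the bright group's mean against, per array of the dim group, the higher of the lowest signal well above background and the probe's own signal. Errors are standard errors (SE) of the model with 3 arrays per group, or standard deviations (SD) where stated, and the number of arrays limits the precision.

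Gene lists were written before the data were examined: jasmonate (JA) biosynthesis, JA signalling and MYC-branch response, JA/ethylene ERF-branch response, acetate and fermentation, glyoxylate cycle, abscisic acid (ABA) and dehydration response, proline and raffinose metabolism, photosynthesis, aquaporins, cell cycle and cell wall expansion, senescence, salicylic acid defence, aliphatic glucosinolates, indolic glucosinolates, anthocyanin and flavonoid synthesis, heat shock, iron homeostasis, phosphate starvation response, histone acetylation enzymes, circadian clock, flower and pollen markers, root markers and seed storage markers. Of 327 members 309 were tested, in 22 of 23 lists, and no seed storage marker was, so that list has no result. Lists were tested with camera in limma at a preset correlation of 0.01 and adjusted over the lists of a comparison, and again with a correlation estimated from the data. P values of lists come from this test. A list test compares the list with all other genes, so its members' own calls are given beside it.

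The rule for naming genes was also set before the data were examined. For each comparison it took the 5 largest increases and 5 largest decreases among called genes with a symbol, well above background on all arrays and with no overlap between replicates of the groups; up to 4 members with the smallest adjusted p of each list that passed or had at least 3 called members; 16 fixed genes (15 tested, since the spots of MYC2 were marked as outliers); and up to 3 at-least folds in each direction. The text prints part of these, mainly genes whose call held under the alternatives tried.

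Alternatives set before the data were examined were quantile normalization, normexp background correction (offset 50) of the mean and background intensity, the deposited series matrix values, no background filter, only probes well above background on all arrays (the strict filter), slide as a fixed term (the slide block) or random term, replicate number as a block, only the arrays of the groups compared, the mean of a gene's probes, eBayes without a trend, an estimated correlation for the lists, and leaving out each array in turn. After the data were seen, spike-in scaling (subtracting each array's mean log2 signal of 10 added control RNA probes), scan day as a block, and a model without the water plants at day 12 were added, together with lists of other flower genes, of rapid wound and touch response genes, and of chloroplast and mitochondrial genome transcripts. The 27 arrays lay on 7 slides scanned on 2 days, and no acid and water array of the same day without water shared a slide, so that effect could be compared within scan days and with the slide block, not within slides.

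The procedure was tested on data simulated from spreads of 21535 genes, 200 changed per fold. Its rates need not hold for real groups. For acid against water plants at day 0 it recovered 56%, 71% and 91% of genes changed 1.5-, 2- and 4-fold, with 3.90% of the calls false. For the interaction at day 6 it recovered 30%, 58% and 83.5%, with 5.21% false.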

Results

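Gene expression was measured in 3 independent samples of each of 9 Arabidopsis groups. Plants were untreated, or had water or 10 mM acetic acid for 9 days and then 0, 6, 9 or 12 days without water. Replicate arrays of a group correlated at 0.965 to 0.992 across genes. Days 6, 9 and 12 have no watered plants of the same age, so plant age and lack of water cannot be told apart in the comparisons with day 0.

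The water plants at day 12 had less signal than all other groups. Their 75th percentile of log2 intensity was 8.22 to 8.58 against 9.60 to 10.20 on the other 24 arrays, and 58.7% to 62.5% of probes were well above background against 66.9% to 72.5%. The 50 brightest probes held 23.2% ± 1.39 (SD, n = 3) of the total intensity, compared with means of 14.3% to 15.7% in other groups. The added control RNA lay 2.12 ± 0.21 (SD, n = 3) log2 units above the 75th percentile, and 0.02 to 0.40 in the means of other groups. Differences that involve this group are therefore relative to the 75th percentile. The files give no RNA integrity values for this or any other group.

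**Figure D1:**
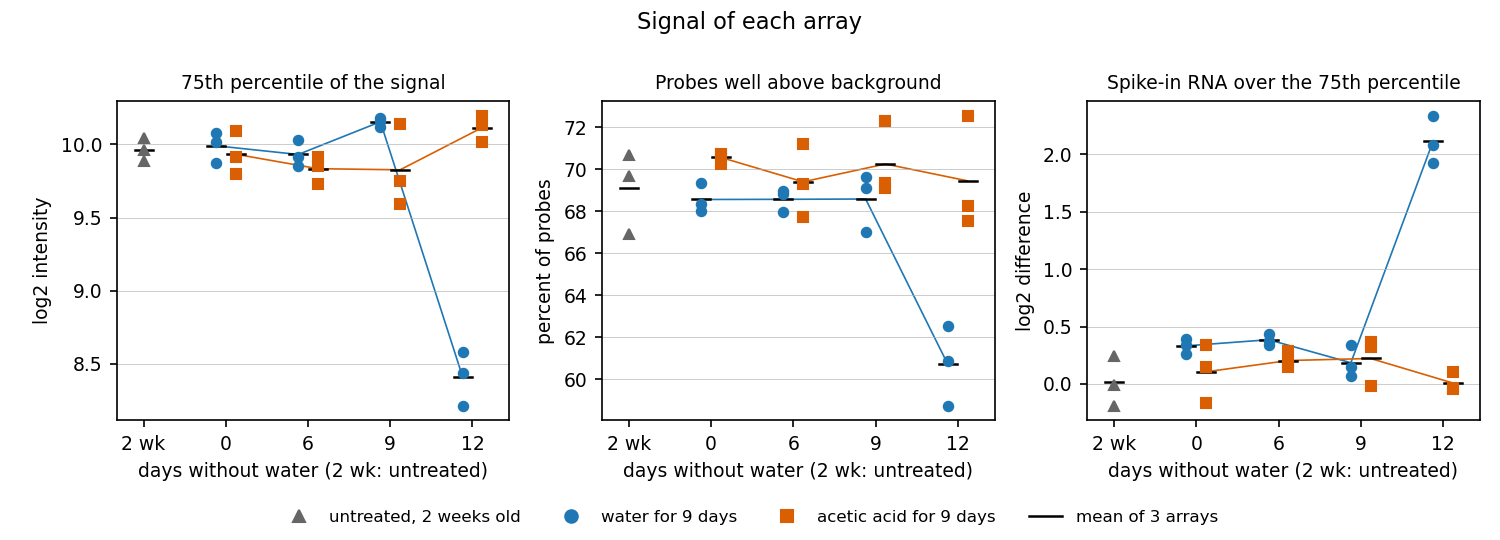
Each point is 1 of 27 arrays by group: the 75th percentile of log2 intensity, the percent of probes well above background, and the mean log2 signal of added control RNA minus the 75th percentile. The 3 arrays of water plants at day 12 have the lowest percentiles, 8.22 to 8.58.

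Other scalings moved the median of all genes by over 0.1 in some comparisons. Spike-in scaling moved acid against water plants by 0.22 at day 0, 0.18 at day 6 and 2.07 at day 12, water plants by 0.14 at day 9 and -1.78 at day 12, acid plants at day 9 by -0.12, the interactions by -0.26 at day 9 and 1.85 at day 12, and water against untreated plants by -0.32. Quantile normalization moved acid against water plants at day 12 by 0.21, acid plants at day 12 by 0.14 and the interaction at day 12 by 0.23. With normexp the shifts were -0.22, 0.16 and -0.36 in acid against water plants at days 6, 9 and 12, 0.32 and 0.63 in water plants at days 6 and 12, 0.22 in acid plants at day 9, and -0.20, 0.17 and -0.38 in the interactions at days 6, 9 and 12.

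The first comparison asked what the acid pretreatment alone had changed. At day 0, the lipid transfer protein gene LTP3 (AT5G59320) was 19.5-fold higher in acid than in water plants (log2 4.28 ± 0.44 SE, n = 3 per group). Iron-deficiency genes were higher, among them BHLH101 (AT5G04150) (log2 1.84 ± 0.33) and the iron sensor BTS (AT3G18290) (0.92 ± 0.15). IMA1 (AT1G47400), which codes for an iron-signalling peptide, was higher by 2.94 ± 0.58, a call that ended when only the 6 arrays compared were used (2.94). The BTB-TAZ genes BT2 (AT3G48360) (-3.29 ± 0.29) and BT1 (AT5G63160) (-2.50 ± 0.23) were lower, as was the phosphodiesterase gene GDPD2 (AT5G41080) (-2.40 ± 0.32). The floral MADS genes SEP1 (AT5G15800) (2.08 ± 0.29) and SEP3 (AT1G24260) (1.67 ± 0.27) were higher. Genes of pollen formation were not well above background in water plants: LTP12 (AT3G51590) was at least 32.4-fold, the acyl-CoA synthetase ACOS5 (AT1G62940) at least 29.6-fold and the tapetum methyltransferase TSM1 (AT1G67990) at least 29.0-fold higher in acid plants. Folds moved over 1.5 times for IMA1 without water replicate 2 (2.12) or 3 (3.84) of day 0 and with the slide block (3.57). Normexp moved IMA1 (2.18) and LTP3 (3.37) as far, and ACOS5 (log2 2.93), LTP12 (3.17) and TSM1 (2.92) to below their bounds.

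List medians are log2 differences, followed in brackets by the medians within scan days 1 and 2, with the slide block and, for drought, within slides that held both groups, with any other alternative that moved the median by over 1.5 times, and the median at bounds, where members with at-least folds are set to their bound and members without a fold to 0. Arrays left out are given by group, replicate and day. Counts of list members adjusted over the list alone are given where they differ from those over all genes. Of 11 flower and pollen marker genes, 6 were higher, 0 lower and 5 did not pass (9 and 0 over the list alone). Their median was 1.94 (scan days 1.84 and 1.59, slide block 1.92, normexp 1.33), adjusted p = 2.78e-06. Iron homeostasis genes had a median of 1.0 (scan days 1.44 and 0.64, slide block 1.14), adjusted p = 5.98e-06. They numbered 15, with 9 higher, 0 lower and 6 not passing (10 and 0 over the list alone). Indolic glucosinolate genes had 2 of 6 higher and 0 lower (6 and 0 over the list alone), median 0.79 (scan days 0.86 and 0.91, slide block 0.78; adjusted p = 1.38e-04). Anthocyanin and flavonoid genes had 5 of 14 higher and 0 lower, median 0.42 (scan days 0.40 and 0.59, slide block 0.42, 0.31 at bounds; adjusted p = 0.00668). The flower and pollen markers differed beside each of these groups, and beside the lists that follow.

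Jasmonate and ethylene ERF-branch genes had 1 of 8 higher and 0 lower (4 and 0 over the list alone), median 1.45 (scan days 1.34 and 1.22, slide block 1.87; adjusted p = 0.00668). Aliphatic glucosinolate genes had 3 of 10 higher and 0 lower (4 and 0 over the list alone), median 0.74 (scan days 0.54 and 1.26, slide block 0.35; adjusted p = 0.00668). Aquaporin genes had 0 of 17 higher and 2 lower, median -0.23 (scan days -0.11 and -0.37, slide block -0.08; adjusted p = 0.00668). Rapid wound and touch genes, a list made after the data were seen, stood beside the ERF-branch genes: 7 of 23 were higher and 1 lower, median 0.80. On the acid arrays of day 0 they lay 0.31, 1.63 and 0.64 above the water plants. Some list calls ended with the strict filter for ERF-branch (0.35) and aliphatic glucosinolate (1.27) and with the slide block for aquaporin (-0.08) and aliphatic glucosinolate (0.35). Further calls ended without acid replicate 2 of day 0 for ERF-branch (1.15) and aliphatic glucosinolate (0.70), without water replicate 3 of day 0 for ERF-branch (1.27) and aquaporin (-0.19) and without water replicate 2 of day 0 for aliphatic glucosinolate (0.54). With an estimated correlation, 1 of the 84 list calls of the 14 comparisons held, that of the flower and pollen markers at day 0 (adjusted p = 0.0393), and the other 83 did not pass.

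Calls were made for 2436 of 21535 genes, 1426 higher and 1010 lower, and 496 and 160 of these differed at least 2-fold. Of the 2436, 2148 were well above background on every array compared and 19 on none, and the slide block gave 705 calls. Leaving out replicate 2 of the water plants gave 928 calls and leaving out replicate 3 of the acid plants 1606. With spike-in scaling 2233 higher and 128 lower genes were called.

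At day 6, the question was how acid plants differed from water plants early in drought. The lipid transfer protein gene LTP4 (AT5G59310) was 5.19-fold higher in acid plants (log2 2.37 ± 0.45 SE, n = 3). Jasmonate-related genes were higher, with CLH1 (AT1G19670) at 2.22 ± 0.47, and the repressor genes JAZ9 (AT1G70700) at 1.07 ± 0.24 and JAZ12 (AT5G20900) at 0.56 ± 0.10. The dehydration genes RD26 (AT4G27410) (1.01 ± 0.15), RD20 (AT2G33380) (0.95 ± 0.17) and HB7 (AT2G46680) (0.90 ± 0.18) were also higher. ACN1 (AT3G16910), an acetate-activating enzyme gene, was higher by 0.67 ± 0.08.

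Jasmonate signalling and MYC-branch genes had a median of 0.86 (scan days 0.40 and 1.09, slide block 1.02), adjusted p = 8.11e-07. They numbered 20, with 11 higher, 0 lower and 9 not passing (12 and 0 over the list alone). Among 15 jasmonate biosynthesis genes, 3 were higher, 0 lower and 12 not passing (8 and 1 over the list alone). This gave a median of 0.39 (scan days 0.18 and 0.69, slide block 0.31), adjusted p = 0.0193. For jasmonate and ethylene ERF-branch genes, 3 of 8 were higher and 0 lower (5 and 1 over the list alone), median 1.61 (scan days 0.76 and 1.55, slide block 2.04; adjusted p = 0.0488). ABA and dehydration response genes had 10 of 36 higher and 2 lower (11 and 2 over the list alone), median 0.17 (scan days 0.39 and 0.25, slide block 0.33, 0.15 at bounds; adjusted p = 0.0193). For aliphatic glucosinolate genes, 2 of 10 were higher and 0 lower, median 0.74 (scan days 0.78 and 0.76, slide block 0.36; adjusted p = 0.0193). Rapid wound and touch genes moved with the jasmonate lists: 11 of 23 were higher and 1 lower, with a median of 1.11.

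Calls of lists ended with the strict filter for jasmonate biosynthesis (0.34), ERF-branch (0.02), ABA (0.25) and aliphatic glucosinolate (0.89). The slide block ended that for aliphatic glucosinolate (0.36). The ERF-branch call also ended with quantile normalization (1.69), normexp (0.30), spike-in scaling (1.78) and the scan day block (1.65). It ended without the water plants at day 12 too (1.61). Single arrays also mattered, with calls ending without acid replicate 2 of day 6 for jasmonate biosynthesis (0.31) and ERF-branch (1.40), without acid replicate 3 of day 6 for jasmonate biosynthesis (0.36), ERF-branch (1.52), ABA (0.19) and aliphatic glucosinolate (0.76), without water replicate 2 of day 6 for jasmonate biosynthesis (0.34) and ERF-branch (1.55), without water replicate 3 of day 6 for jasmonate biosynthesis (0.32) and ERF-branch (1.46) and without water replicate 1 of day 6 for ABA (0.10). Cell cycle and cell wall expansion genes did not pass as a list (median -0.87, adjusted p = 0.0858), with 5 of 11 lower.

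In all, 4509 of 21535 genes passed, 1966 of them higher and 2543 lower, with 376 and 624 at least 2-fold apart. Of these, 4231 were well above background on every array compared and 29 on none, and 956 were called with the slide block. There were 2223 calls without replicate 1 of the acid plants at day 6, and 2519 and 2685 without replicate 1 or 2 of the water plants at day 6. Spike-in scaling gave 1960 higher and 396 lower calls.

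At day 9, jasmonate genes again differed between acid and water plants. The ERF gene RRTF1 (AT4G34410) was 139.9-fold higher in acid plants (log2 7.13 ± 0.60 SE, n = 3), MYB15 (AT3G23250) 76.3-fold (6.25 ± 0.70) and ORA47 (AT1G74930) 64.8-fold (6.02 ± 0.50). The repressor genes JAZ7 (AT2G34600) (4.34 ± 0.41), JAZ1 (AT1G19180) (3.62 ± 0.28) and JAZ10 (AT5G13220) (2.82 ± 0.48) were higher, as were LOX3 (AT1G17420) (3.80 ± 0.35) and OPR3 (AT2G06050) (2.65 ± 0.24) of jasmonate synthesis.

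The auxin synthesis gene YUC9 (AT1G04180) (-3.76 ± 0.32), the aquaporin gene TIP2;1 (AT3G16240) (-1.46 ± 0.25) and the wall enzyme gene XTH4 (AT2G06850) (-2.11 ± 0.29) were lower in acid plants. ADH1 (AT1G77120), for alcohol dehydrogenase, was lower (-0.89 ± 0.17), while ACN1 was higher by 0.69 ± 0.08. PDC1 (AT4G33070), for pyruvate decarboxylase, was 8.88-fold lower (-3.15 ± 0.56), with 2 of 3 acid arrays well above background, and its call ended with normexp (-0.77). RTFL12 (AT4G13395) was at least 37.7-fold higher. Folds moved over 1.5 times without water replicate 3 of day 9 for PDC1 (-2.42). The slide block did so for JAZ10 (3.41) and MYB15 (7.46). Normexp moved MYB15 (4.99), YUC9 (-1.96) and, below its bound, RTFL12 (log2 3.25).

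Among 20 jasmonate signalling and MYC-branch genes, 12 were higher, 1 lower and 7 not passing (13 and 1 over the list alone). This gave a median of 1.0 (scan days 0.90 and 1.09, slide block 1.68), adjusted p = 3.89e-06. Of 15 jasmonate biosynthesis genes, 6 were higher, 0 lower and 9 did not pass (6 and 1 over the list alone). Here the median was 0.68 (scan days 0.54 and 0.94, slide block 0.68), adjusted p = 1.47e-04. For indolic glucosinolate genes, 6 of 6 were higher and 0 lower, median 1.07 (scan days 0.87 and 1.39, slide block 1.23; adjusted p = 1.32e-04). Of 23 rapid wound and touch genes 19 were higher and 0 lower, with a median of 3.25, beside the jasmonate lists.

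The test called 4477 of 21535 genes (2019 higher, 2458 lower), of which 906 and 591 differed at least 2-fold. Of the 4477, 4097 were well above background on every array compared and 19 on none, and the slide block gave 3137 calls. Without replicate 2 of the water plants at day 9 there were 2891 calls. Normexp gave 1047 higher and 810 lower calls.

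**Figure D2:**
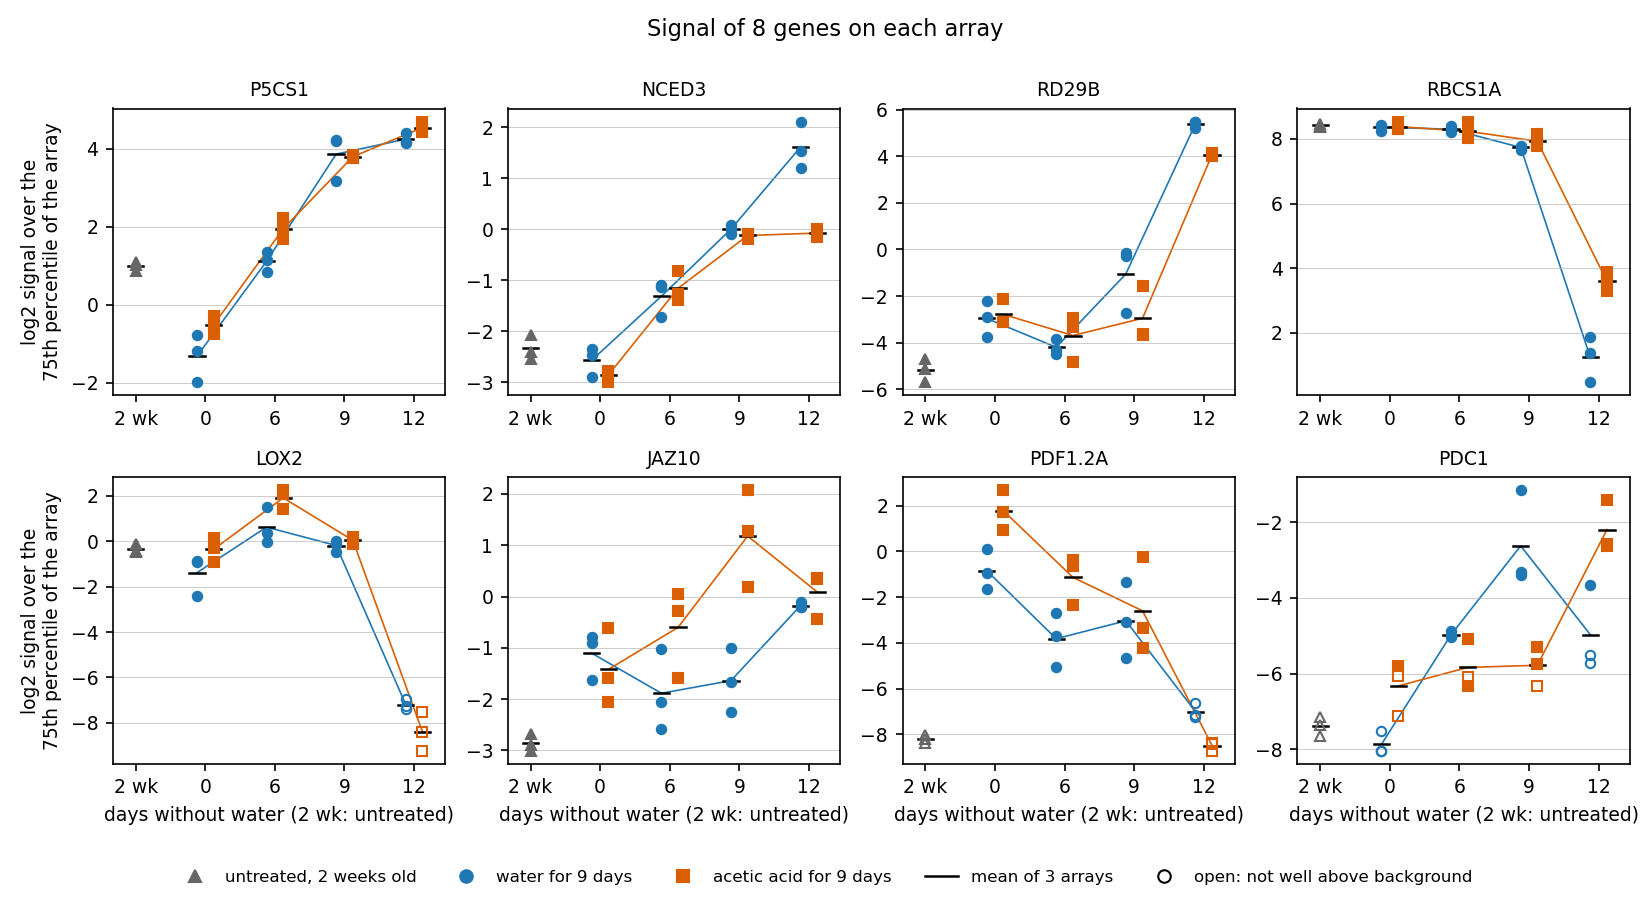
Points are single arrays and lines join group means of log2 intensity minus the 75th percentile over days without water, for 8 genes in water, acid and untreated plants; open symbols mark spots not well above background. JAZ10 is higher in acid plants at day 9 (2.82 ± 0.48).

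Day 12 had the most calls between acid and water plants. MYB47 (AT1G18710) was 36.0-fold higher in acid plants (log2 5.17 ± 0.37 SE, n = 3), the ferric reductase gene FRO8 (AT5G50160) 19.9-fold (4.32 ± 0.16) and the tonoplast aquaporin gene TIP1;2 (AT3G26520) 5.76-fold (2.53 ± 0.18). Photosynthesis genes were higher, with the Rubisco small subunit genes RBCS1A (AT1G67090) at 2.34 ± 0.22 and RBCS3B (AT5G38410) at 1.80 ± 0.16. The clock gene LHY (AT1G01060) (-4.0 ± 0.26) and its relative RVE1 (AT5G17300) (-4.39 ± 0.23) were lower. KCS19 (AT5G04530) was at least 39.2-fold higher and BGAL15 (AT1G31740) at least 8.44-fold lower. NCED3 (AT3G14440), of ABA synthesis, was lower (-1.69 ± 0.20), but higher with spike-in scaling (0.39). That scaling shifted each difference here by 2.07. Without water replicate 3 of day 12, BGAL15 was at least 5.63-fold lower. Normexp moved folds over 1.5 times for FRO8 (2.76), LHY (-2.92), MYB47 (2.73) and RVE1 (-3.61), and below their bounds for BGAL15 (log2 -2.35) and KCS19 (2.42).

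Of 33 photosynthesis genes, 26 were higher, 0 lower and 7 did not pass. Here the median was 0.87 (scan days 0.51 and 1.09, slide block 0.71, quantile 1.58, spike-in scaling 2.95), adjusted p = 1.12e-04. Among 12 heat shock genes, 0 were higher, 10 lower and 2 not passing. This gave a median of -2.75 (scan days -2.38 and -3.03, slide block -3.21, spike-in scaling -0.67), adjusted p = 0.0353. Both lists differed beside the low signal of the water plants at day 12. The heat shock call ended with no filter (-2.75) and with the strict filter (-2.03). It also ended without acid replicate 2 (-2.43), water replicate 1 (-2.57) or water replicate 2 (-2.52) of day 12.

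Calls were made for 15208 of 21535 genes, 7093 higher and 8115 lower, and 3734 and 4069 of these differed at least 2-fold. Of the 15208, 11818 were well above background on every array compared and 927 on none, and the slide block gave 13935 calls. All 927 genes above background on no array were lower in acid plants. Among genes well above background on every array, 5355 were higher and 6463 lower. The balance depended on scaling: 18510 higher and 174 lower with spike-in scaling, 3448 higher and 10520 lower with normexp and 8102 higher and 5499 lower with quantile normalization.

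Within water plants, day 6 was compared with day 0 for the early drought response. LTP3 was 46.6-fold higher at day 6 (log2 5.54 ± 0.44 SE, n = 3). CYP79F1 (AT1G16410) (5.20 ± 0.48) and BAT5 (AT4G12030) (3.09 ± 0.30) of aliphatic glucosinolate synthesis rose, as did COR15A (AT2G42540) (5.13 ± 0.43) of the dehydration response. P5CS1 (AT2G39800), for proline synthesis, rose 5.40-fold (2.43 ± 0.25) and NCED3 2.38-fold (1.25 ± 0.20), while the proline dehydrogenase gene PRODH1 (AT3G30775) fell (-2.54 ± 0.32). LOX2 (AT3G45140) of jasmonate synthesis rose (2.01 ± 0.43). PDC1 was at least 2.17-fold higher, and BT2 fell (-5.76 ± 0.29). Folds moved by over 1.5 times without water replicate 2 of day 0 for COR15A (4.39) and CYP79F1 (4.61) and without water replicate 3 of day 0 for COR15A (5.78). Normexp moved CYP79F1 (4.59), LTP3 (4.46) and PDC1 (1.70) as far.

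22 of 36 ABA and dehydration response genes rose, 4 fell and 10 did not pass (1 of the changed genes not well above background in either group). Their median was 1.36 (scan days 1.04 and 1.47, slide block 1.36, slides 1.04 to 1.45, 1.11 at bounds), adjusted p = 1.33e-05. Aliphatic glucosinolate genes had a median of 3.02 (scan days 2.83 and 3.12, slide block 2.97, slides 2.58 to 3.56), adjusted p = 1.97e-05. They numbered 10, with 9 higher, 0 lower and 1 not passing (10 and 0 over the list alone). For anthocyanin and flavonoid genes, 11 of 14 were higher and 0 lower, median 2.01 (scan days 2.48 and 1.70, slide block 2.01, slides 1.65 to 2.48, 1.54 at bounds; adjusted p = 1.97e-05). Jasmonate biosynthesis genes had 11 of 15 higher and 1 lower (12 and 1 over the list alone), median 1.05 (scan days 1.31 and 1.12, slide block 1.05, slides 1.07 to 1.31; adjusted p = 0.00140). Photosynthesis genes had 24 of 33 higher and 0 lower, median 0.60 (scan days 0.62 and 0.58, slide block 0.60, slides 0.32 to 0.83; adjusted p = 8.39e-05). Indolic glucosinolate genes had 5 of 6 higher and 0 lower, median 0.99 (scan days 0.97 and 1.04, slide block 0.99, slides 0.97 to 1.11; adjusted p = 0.00633). Beside the jasmonate list, 7 of 23 rapid wound and touch genes were higher and 1 lower, median 0.49. Among alternatives, list calls ended with normexp for photosynthesis (0.33) and with the strict filter for aliphatic glucosinolate (3.09).

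In all, 10373 of 21535 genes passed, 4974 of them higher and 5399 lower, with 2019 and 1215 at least 2-fold apart. Of these, 9592 were well above background on every array compared and 60 on none, and 10538 were called with the slide block. Normexp gave 6580 higher and 3511 lower calls.

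By day 9, LTP3 was 1215-fold higher than at day 0 in water plants (log2 10.25 ± 0.44 SE, n = 3). P5CS1 was 36.3-fold higher (5.18 ± 0.25), RD20 27.5-fold (4.78 ± 0.17) and NCED3 5.92-fold (2.57 ± 0.20). The sulphur-deficiency gene ATSDI1 (AT5G48850) rose (6.13 ± 0.30), as did the heat shock gene HSP70-4 (AT3G12580) (3.35 ± 0.30). PDC1 was at least 11-fold higher. PRODH1 (-5.87 ± 0.32), GDPD2 (-6.78 ± 0.32) and the wall enzyme gene XTH15 (AT4G14130) (-5.87 ± 0.32) fell. Folds moved over 1.5 times without water replicate 3 of day 9 for PDC1 (at least 6.62-fold). Normexp moved ATSDI1 (4.31), GDPD2 (-5.84), LTP3 (9.33) and, below its bound, PDC1 (log2 1.76).

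Of 36 ABA and dehydration response genes, 32 rose, 2 fell and 2 did not pass. Their median was 2.56 (scan days 2.56 and 2.61, slide block 2.65, slides 2.56 to 3.30, normexp 1.96, 2.46 at bounds), adjusted p = 1.44e-14. Anthocyanin and flavonoid genes had a median of 2.93 (scan days 2.93 and 3.04, slide block 3.08, slides 2.93 to 4.16, normexp 1.64, strict filter 1.94, 2.66 at bounds), adjusted p = 6.05e-07. They numbered 14, with 13 higher, 0 lower and 1 not passing. Aliphatic glucosinolate genes had 10 of 10 higher and 0 lower, median 2.96 (scan days 2.70 and 3.1, slide block 2.70, slides 2.70 to 3.43; adjusted p = 9.83e-05). For jasmonate biosynthesis genes, 11 of 15 were higher and 0 lower (12 and 0 over the list alone), median 1.03 (scan days 0.74 and 1.44, slide block 0.89, slides 0.74 to 0.88; adjusted p = 0.00118). Jasmonate signalling and MYC-branch genes had 12 of 20 higher and 1 lower, median 0.66 (scan days 0.53 and 0.75, slide block 0.63, slides 0.35 to 0.53; adjusted p = 0.0154). Senescence genes had 9 of 15 higher and 1 lower, median 0.66 (scan days 0.94 and 0.67, slide block 0.56, slides 0.31 to 0.94; adjusted p = 0.0322). Cell cycle and cell wall expansion genes had 0 of 11 higher and 8 lower, median -1.46 (scan days -1.43 and -1.48, slide block -1.26, slides -1.43 to -1.37; adjusted p = 0.0313). Phosphate starvation genes had 5 of 8 higher and 1 lower, median 0.99 (scan days 0.88 and 1.06, slide block 0.82, slides 0.76 to 0.88; adjusted p = 0.0474). Beside the jasmonate lists, 9 of 23 rapid wound and touch genes were higher and 4 lower, median 0.59.

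List calls ended with the strict filter for senescence (0.47) and aliphatic glucosinolate (3.09), with the slide block for senescence (0.56) and phosphate starvation (0.82), with quantile normalization for phosphate starvation (1.04) and with spike-in scaling for phosphate starvation (1.13). Single arrays also mattered, with calls ending without water replicate 3 of day 0 for jasmonate signalling (0.58), cell cycle (-1.50), senescence (0.55) and phosphate starvation (1.05), without water replicate 3 of day 9 for cell cycle (-1.17) and phosphate starvation (0.74) and without water replicate 1 of day 0 for phosphate starvation (0.96). The test called 12733 of 21535 genes (5756 higher, 6977 lower), of which 2764 and 2628 differed at least 2-fold. Of the 12733, 11355 were well above background on every array compared and 77 on none, and the slide block gave 12397 calls. Spike-in scaling gave 5700 higher and 4161 lower calls.

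At day 12, dehydration genes of water plants had risen further from day 0, relative to arrays of low signal. RD29B (AT5G52300) was 329-fold higher (log2 8.36 ± 0.61 SE, n = 3) and RD20 616-fold (9.27 ± 0.17). LEA7 (AT1G52690), for a late embryogenesis abundant protein, was at least 5.32e+04-fold higher. HSP70-4 rose by 9.93 ± 0.30 and ADH1 by 7.88 ± 0.17. RBCS1A had a log2 difference of -7.12 ± 0.22, the aquaporin gene TIP2;1 of -10.84 ± 0.25 and the arabinogalactan gene FLA13 (AT5G44130) of -9.84 ± 0.21. Alternatives moved folds over 1.5 times, with normexp for FLA13 (-7.65), HSP70-4 (9.31), RD29B (7.43) and TIP2;1 (-9.70) and with the mean of probes for RBCS1A (-7.78) and TIP2;1 (-10.25).

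Among 36 ABA and dehydration response genes, 34 rose, 2 fell and 0 did not pass. Here the median was 5.96 (scan days 5.85 and 5.91, slide block 6.09, 1 slide 5.85, normexp 4.86, strict filter 4.68, spike-in scaling 4.18), adjusted p = 1.71e-10. 0 of 33 photosynthesis genes rose, 33 fell and 0 did not pass. Their median was -4.21 (scan days -3.71 and -4.61, slide block -4.15, 1 slide -3.71, probe mean -5.19, spike-in scaling -5.99), adjusted p = 1.71e-10. For aquaporin genes, 1 of 17 was higher and 15 lower, median -3.82 (scan days -3.29 and -4.06, slide block -3.88, 1 slide -3.29, spike-in scaling -5.60, -3.60 at bounds; adjusted p = 2.06e-04). Heat shock genes had 12 of 12 higher and 0 lower, median 7.51 (scan days 7.87 and 7.54, slide block 7.66, 1 slide 7.87, normexp 6.12, spike-in scaling 5.73; adjusted p = 0.00103). For cell cycle and cell wall expansion genes, 0 of 11 were higher and 11 lower, median -4.01 (scan days -4.11 and -4.07, slide block -3.66, 1 slide -4.11, normexp -1.15, -3.28 at bounds; adjusted p = 0.0103). The low signal of the water plants at day 12 enters each of these differences.

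For senescence genes, 12 of 15 were higher and 3 lower, median 3.15 (scan days 3.25 and 3.09, slide block 2.97, 1 slide 3.25, spike-in scaling 1.37; adjusted p = 0.0242). Acetate and fermentation genes had 7 of 9 higher and 0 lower, median 2.85 (scan days 2.31 and 2.74, slide block 2.12, 1 slide 2.31, no filter 1.70, spike-in scaling 1.07, 1.12 at bounds; adjusted p = 0.0242). Proline and raffinose metabolism genes had 9 of 11 higher and 2 lower, median 2.41 (scan days 2.38 and 2.42, slide block 2.49, 1 slide 2.38, spike-in scaling 0.63; adjusted p = 0.0331). For aliphatic glucosinolate genes, 0 of 10 were higher and 10 lower, median -3.53 (scan days -3.80 and -3.42, slide block -3.77, 1 slide -3.80, quantile -4.14, series matrix -2.87, -2.49 at bounds; adjusted p = 0.0272). For indolic glucosinolate genes, 0 of 6 were higher and 6 lower, median -2.81 (scan days -2.77 and -3.20, slide block -2.67, 1 slide -2.77, normexp -1.60, -2.68 at bounds; adjusted p = 0.0326). The low signal stands beside these lists too. Acetate genes moved over 1.5 times without water replicate 3 of day 12 (2.25).

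Some list calls ended with quantile normalization for acetate (2.59) and proline and raffinose (1.97), with normexp for acetate (2.02), proline and raffinose (2.14) and aliphatic glucosinolate (-0.41), with the strict filter for acetate (2.85), proline and raffinose (2.19), cell cycle (-4.74), senescence (2.92), aliphatic glucosinolate (-2.11), indolic glucosinolate (-2.11) and heat shock (6.66), with no filter for proline and raffinose (2.41) and with spike-in scaling for cell cycle (-5.79), aliphatic glucosinolate (-5.31) and indolic glucosinolate (-4.59). Calls were made for 18613 of 21535 genes, 9012 higher and 9601 lower, and 6696 and 7513 of these differed at least 2-fold. Of the 18613, 13475 were well above background on every array compared and 185 on none, and the slide block gave 18119 calls. Other scalings gave 3241 higher and 15554 lower (spike-in scaling) and 10717 higher and 6001 lower (normexp).

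Acid plants were compared with their own day 0. At day 6, P5CS1 was 5.51-fold (log2 2.46 ± 0.25 SE, n = 3) and NCED3 3.24-fold higher (1.70 ± 0.20). BAT5 rose by 2.71 ± 0.30. The anthocyanin regulator gene PAP1 (AT1G56650) rose by 4.81 ± 0.33, LOX2 by 2.27 ± 0.43 and JAZ7 by 3.42 ± 0.41. IMA1 (-4.28 ± 0.58), BHLH101 (-3.30 ± 0.33) and SEP3 (-2.09 ± 0.27) fell. LTP12 was at least 36.0-fold and ACOS5 at least 32.8-fold lower. Normexp moved folds over 1.5 times for IMA1 (-2.96) and PAP1 (3.55), and below their bounds for LTP12 (log2 -3.07) and ACOS5 (-2.74).

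ABA and dehydration response genes had a median of 1.07 (scan days 1.09 and 1.15, slide block 1.07, slides 0.91 to 1.27, 0.94 at bounds), adjusted p = 1.20e-08. They numbered 36, with 24 higher, 0 lower and 12 not passing (25 and 0 over the list alone) (1 of the changed genes not well above background in either group). Among 10 aliphatic glucosinolate genes, 9 were higher, 0 lower and 1 not passing (10 and 0 over the list alone). This gave a median of 2.63 (scan days 2.72 and 2.44, slide block 2.63, slides 2.18 to 3.26), adjusted p = 3.39e-06. Jasmonate biosynthesis genes had 13 of 15 higher and 0 lower, median 1.18 (scan days 1.1 and 1.08, slide block 1.18, slides 0.88 to 1.25; adjusted p = 1.64e-04). For jasmonate signalling and MYC-branch genes, 13 of 20 were higher and 1 lower, median 0.92 (scan days 0.85 and 1.26, slide block 0.92, slides 0.84 to 1.26; adjusted p = 4.52e-04). Anthocyanin and flavonoid genes had 8 of 14 higher and 0 lower, median 0.96 (scan days 0.72 and 1.44, slide block 0.96, slides 0.53 to 1.44, 0.72 at bounds; adjusted p = 6.01e-04). Flower and pollen marker genes had 0 of 11 higher and 9 lower, median -3.60 (scan days -3.78 and -3.05, slide block -3.60, slides -4.05 to -3.05, quantile -2.44, normexp -1.25, no filter -2.77, -2.31 at bounds; adjusted p = 4.20e-04). Beside the jasmonate lists, 9 of 23 rapid wound and touch genes were higher and 0 lower, median 0.50. The acid plants at day 0 had higher flower markers than water plants (median 1.94), and they are the reference of each of these differences.

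Iron homeostasis genes had 2 of 15 higher and 11 lower, median -1.48 (scan days -1.54 and -1.34, slide block -1.48, slides -1.74 to -1.34; adjusted p = 0.00242). For photosynthesis genes, 12 of 33 were higher and 0 lower (6 and 0 over the list alone), median 0.38 (scan days 0.44 and 0.24, slide block 0.38, slides 0.24 to 0.59; adjusted p = 0.00258). Indolic glucosinolate genes had 5 of 6 higher and 0 lower, median 0.80 (scan days 0.85 and 0.71, slide block 0.80, slides 0.71 to 0.83; adjusted p = 0.0477). The flower markers of the day 0 reference apply to these lists as well. Calls of lists ended with quantile normalization for photosynthesis (0.23) and indolic glucosinolate (0.82), with the strict filter for aliphatic glucosinolate (2.71), indolic glucosinolate (0.93), anthocyanin (0.35), iron (-1.29) and flower and pollen (-3.06), with spike-in scaling for indolic glucosinolate (0.70) and with the scan day block for indolic glucosinolate (0.80). The indolic glucosinolate call also ended without acid replicate 1 (0.74) or 3 (0.84) of day 0 or 2 of day 6 (0.76).

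In all, 10511 of 21535 genes passed, 4435 of them higher and 6076 lower, with 1698 and 2030 at least 2-fold apart. Of these, 9579 were well above background on every array compared and 42 on none, and 10702 were called with the slide block.

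At day 9, RRTF1 was 278-fold higher than at day 0 in acid plants (log2 8.12 ± 0.60 SE, n = 3), and JAZ7 116-fold (6.85 ± 0.41). LOX3 rose by 5.44 ± 0.35 and OPR3 by 3.58 ± 0.24. P5CS1 rose by 4.31 ± 0.25, NCED3 by 2.73 ± 0.20 and RD20 by 3.73 ± 0.17. XTH15 fell (-6.54 ± 0.32). PDC1, which rose in water plants, did not pass in acid plants (0.55 ± 0.56, above background on 2 and 1 of 3 arrays). At day 12 its mean was -2.20 in acid plants (3 of 3 arrays, -6.32 at day 0) and -4.97 in water plants (1 of 3). Folds moved over 1.5 times for RRTF1 without acid replicate 1 (7.25) or 2 (8.95) of day 0. Normexp moved RRTF1 (7.13) and XTH15 (-5.48) as far.

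Among 36 ABA and dehydration response genes, 30 were higher, 1 lower and 5 not passing (30 and 2 over the list alone). This gave a median of 2.44 (scan days 2.42 and 2.36, slide block 2.38, slides 2.37 to 2.42, normexp 1.79, 2.37 at bounds), adjusted p = 9.12e-13. Of 20 jasmonate signalling and MYC-branch genes, 16 rose, 2 fell and 2 did not pass. Their median was 1.56 (scan days 1.36 and 1.56, slide block 1.51, slides 1.40 to 1.52), adjusted p = 2.52e-05. For jasmonate biosynthesis genes, 11 of 15 were higher and 0 lower (12 and 0 over the list alone), median 1.60 (scan days 2.45 and 1.27, slide block 2.17, slides 1.01 to 2.58, strict filter 2.53; adjusted p = 6.55e-05). Aliphatic glucosinolate genes had 9 of 10 higher and 0 lower (10 and 0 over the list alone), median 2.43 (scan days 2.40 and 2.07, slide block 2.45, slides 1.98 to 2.93; adjusted p = 4.30e-04). For anthocyanin and flavonoid genes, 11 of 14 were higher and 1 lower (12 and 1 over the list alone), median 1.81 (scan days 2.26 and 1.01, slide block 1.95, slides 1.74 to 2.79, normexp 1.16, 1.26 at bounds; adjusted p = 4.30e-04). Rapid wound and touch genes had a median of 3.04, with 20 of 23 higher and 1 lower, beside the jasmonate lists. The flower markers of the day 0 acid plants (1.94 above water plants) enter this reference too. Jasmonate biosynthesis genes moved over 1.5 times without acid replicate 1 (0.98) or 2 (2.60) of day 0.

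Cell cycle and cell wall expansion genes had 0 of 11 higher and 10 lower, median -2.31 (scan days -2.58 and -1.68, slide block -2.38, slides -2.61 to -2.35, normexp -1.1; adjusted p = 0.00293). Senescence genes had 8 of 15 higher and 2 lower, median 0.58 (scan days 0.74 and 0.63, slide block 0.65, slides 0.84 to 1.43; adjusted p = 0.0285). For indolic glucosinolate genes, 5 of 6 were higher and 0 lower, median 1.17 (scan days 0.89 and 1.51, slide block 0.97, slides 0.83 to 1.0; adjusted p = 0.0285). The alternatives ended list calls with normexp for senescence (0.57) and with the strict filter for senescence (0.49), aliphatic glucosinolate (2.17), indolic glucosinolate (0.99) and anthocyanin (0.62). Without acid replicate 3 of day 9 the indolic glucosinolate call ended (0.95). The test called 13724 of 21535 genes (5756 higher, 7968 lower), of which 2863 and 3415 differed at least 2-fold. Of the 13724, 12270 were well above background on every array compared and 44 on none, and the slide block gave 13537 calls.

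At day 12, RD29B was 117-fold (log2 6.87 ± 0.61 SE, n = 3) and RD20 91.7-fold higher (6.52 ± 0.17) than at day 0 in acid plants. LTP4 rose by 9.45 ± 0.45 and ADH1 by 5.85 ± 0.17. LEA7 was at least 1.89e+04-fold higher. RBCS1A (-4.79 ± 0.22), TIP2;1 (-9.51 ± 0.25) and FLA13 (-9.52 ± 0.21) fell. LOX2 was at least 72.4-fold and the defensin gene PDF1.2A (AT5G44420) at least 321-fold lower. Folds moved over 1.5 times with quantile normalization for LTP4 (10.33) and RD20 (7.25) and with the mean of probes for RBCS1A (-5.55). Normexp moved FLA13 (-8.01) and, below their bounds, LEA7 (log2 11.70), LOX2 (-3.84) and PDF1.2A (-5.91).

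35 of 36 ABA and dehydration response genes rose, 1 fell and 0 did not pass. Their median was 4.72 (scan days 4.93 and 4.56, slide block 4.70, 1 slide 4.88, strict filter 3.77), adjusted p = 2.64e-12. Of 33 photosynthesis genes, 0 rose, 33 fell and 0 did not pass. Their median was -3.60 (scan days -3.50 and -3.66, slide block -3.56, 1 slide -3.45), adjusted p = 4.07e-12. Aquaporin genes had 0 of 17 higher and 15 lower (0 and 16 over the list alone), median -3.42 (scan days -3.64 and -3.07, slide block -3.68, 1 slide -3.59, normexp -2.81; adjusted p = 9.25e-06). For cell cycle and cell wall expansion genes, 0 of 11 were higher and 11 lower, median -4.93 (scan days -4.95 and -5.48, slide block -5.29, 1 slide -4.99, normexp -3.30, strict filter -5.65, -4.66 at bounds; adjusted p = 2.76e-04). For heat shock genes, 12 of 12 were higher and 0 lower, median 5.07 (scan days 6.33 and 5.09, slide block 5.14, 1 slide 6.04, normexp 2.54, 4.56 at bounds; adjusted p = 0.00131). For senescence genes, 11 of 15 were higher and 3 lower, median 2.99 (scan days 3.03 and 2.98, slide block 2.95, 1 slide 3.01; adjusted p = 0.0117). The day 0 reference held higher flower markers (1.94) beside these and the next lists. Heat shock genes moved over 1.5 times without acid replicate 1 (4.32) or 2 (5.80) of day 12.

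Salicylic acid defence genes had 1 of 15 higher and 13 lower, median -3.12 (scan days -3.17 and -2.80, slide block -3.99, 1 slide -2.95, normexp -2.10; adjusted p = 0.0159). For aliphatic glucosinolate genes, 0 of 10 were higher and 10 lower, median -5.13 (scan days -4.40 and -6.60, slide block -4.69, 1 slide -3.43, normexp -3.18, -4.59 at bounds; adjusted p = 0.00132). Indolic glucosinolate genes had 0 of 6 higher and 6 lower, median -2.87 (scan days -2.80 and -2.89, slide block -2.89, 1 slide -2.68; adjusted p = 0.0120). Anthocyanin and flavonoid genes had 11 of 14 higher and 2 lower, median 2.28 (scan days 2.91 and 1.99, slide block 2.36, 1 slide 2.64, normexp 1.09, 2.21 at bounds; adjusted p = 0.0290). For proline and raffinose metabolism genes, 7 of 11 were higher and 2 lower, median 1.94 (scan days 1.81 and 1.96, slide block 1.90, 1 slide 2.17; adjusted p = 0.0290). Folds moved by over 1.5 times without acid replicate 1 of day 0 for aliphatic glucosinolate genes (-6.50).

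Among alternatives, list calls ended with the strict filter for proline and raffinose (1.91), senescence (2.85), salicylic acid (-2.13), aliphatic glucosinolate (-4.62), anthocyanin (1.47) and heat shock (4.18). The anthocyanin call ended without acid replicate 1 of day 12 (2.06). In all, 17429 of 21535 genes passed, 8466 of them higher and 8963 lower, with 4955 and 6347 at least 2-fold apart. Of these, 14299 were well above background on every array compared and 58 on none, and 16855 were called with the slide block.

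**Figure D3:**
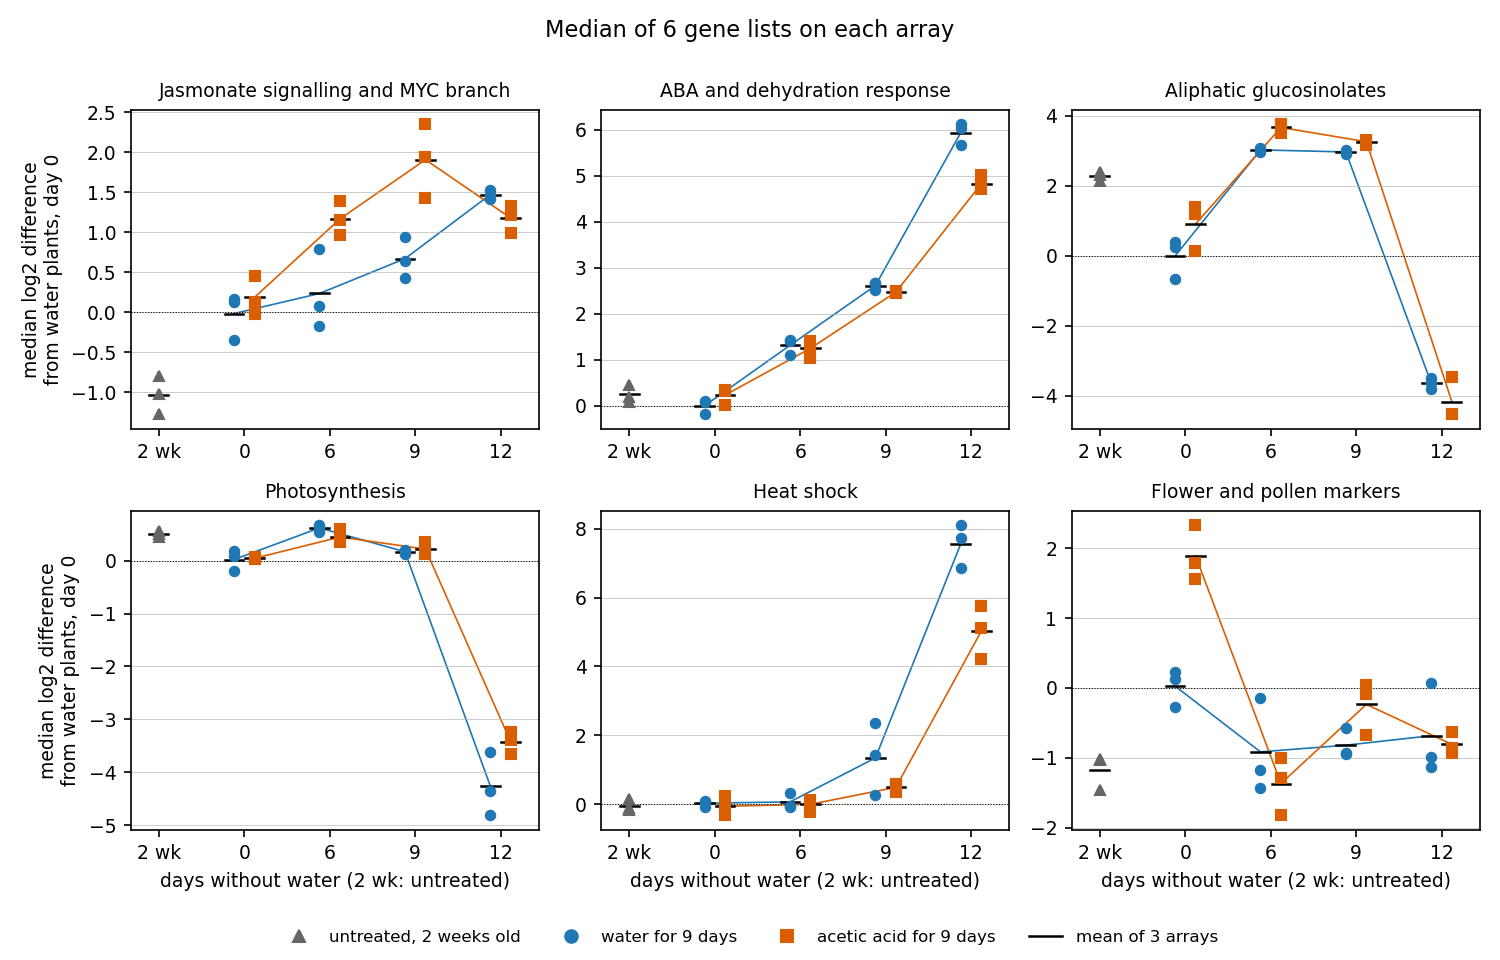
Points are the median log2 intensity of 6 gene lists on each array, relative to the mean of water plants at day 0, by days without water for water, acid and untreated plants. Photosynthesis genes are lowest at day 12 in both pretreatments, with medians of -4.21 in water and -3.60 in acid plants against day 0.

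The drought responses of water and acid plants, which share no arrays, overlapped (counts expected if independent in brackets). At day 6, 3347 (1024) genes rose and 3938 (1523) fell in both, while 79 that rose and 25 that fell in water plants went the other way in acid plants. At day 9 the shared genes were 4398 (1538) higher and 5922 (2582) lower, and at day 12 7283 (3543) and 7691 (3996). Between days, acid against water plants shared 477 (130) higher and 324 (119) lower genes at days 0 and 6, 594 (184) and 919 (290) at days 6 and 9, and 475 (665) and 1053 (926) at days 9 and 12.

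The interaction asked whether acid plants responded to drought differently from water plants; positive values mean a larger rise or smaller fall in acid plants; genes counted as higher or lower here have a positive or negative difference, and list members above background in all 4 groups are called measured. At day 6, LTP3 rose less in acid plants (log2 -3.42 ± 0.62 SE, n = 3 in each of 4 groups), while BT1 (2.67 ± 0.32) and the branched-chain amino acid gene BCAT-2 (AT1G10070) (1.99 ± 0.27) fell less. LTP3 was already higher (4.28) and BT1 lower in acid plants at day 0, which enters these values. Folds also moved over 1.5 times with normexp for LTP3 (-2.38). Among 20 jasmonate signalling and MYC-branch genes, 4 were positive, 0 negative and 16 not passing (6 and 0 over the list alone). Here the median was 0.53 (scan days 0.31 and 0.76, slide block 0.53), adjusted p = 4.90e-05. Beside them, 3 of 23 rapid wound and touch genes were positive and 0 negative, median 0.20. 0 of 11 flower and pollen marker genes were positive, 6 negative and 5 did not pass (0 and 8 over the list alone). Their median was -1.53 (scan days -1.30 and -1.94, slide block -1.53, -1.48 over the 3 measured), adjusted p = 2.72e-05. The flower markers of day 0 enter each interaction through the acid reference. List calls ended with the strict filter for flower and pollen (-1.50).

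The test called 1269 of 21535 genes (415 higher, 854 lower), of which 148 and 507 differed at least 2-fold. Of the 1269, 1092 were well above background on every array compared and 4 on none, and the slide block gave 1277 calls. Leaving out an array gave 603 calls for replicate 1 of the acid plants at day 6, 780 for replicate 3 of the acid plants at day 0, 667 for replicate 2 of the water plants at day 0, and 653 and 741 for replicates 1 and 2 of the water plants at day 6. Normexp gave 147 higher and 156 lower calls.

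At day 9, JAZ7 (5.29 ± 0.58), JAZ1 (3.04 ± 0.40) and OPR3 (2.15 ± 0.34) of the jasmonate pathway rose more in acid plants, and GDPD2 fell less (5.79 ± 0.46). LTP3 (-6.13 ± 0.62), ADH1 (-1.34 ± 0.24) and the chalcone synthase gene CHS (AT5G13930) (-3.01 ± 0.68) had lower responses in acid plants. Folds moved over 1.5 times without water replicate 2 of day 9 for CHS (-2.34). Normexp moved CHS (-1.96), GDPD2 (5.06) and LTP3 (-5.32) as far.

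Of 20 jasmonate signalling and MYC-branch genes, 9 were positive, 0 negative and 11 did not pass (11 and 3 over the list alone). Their median was 0.62 (scan days 0.93 and 0.74, slide block 0.59), adjusted p = 4.86e-05. Among 15 jasmonate biosynthesis genes, 6 were positive, 0 negative and 9 not passing. This gave a median of 0.16 (scan days 0.57 and 0.07, slide block 0.41), adjusted p = 0.00467. For anthocyanin and flavonoid genes, 0 of 14 were positive and 2 negative (0 and 6 over the list alone), median -1.22 (scan days -0.54 and -1.50, slide block -0.64, normexp -0.32, -1.15 over the 9 measured; adjusted p = 0.00398). Rapid wound and touch genes moved with the jasmonate lists, at a median of 2.48 with 18 of 23 higher and 0 lower. The flower markers, LTP3 and GDPD2 of day 0 belong to this reference too. With spike-in scaling the median changed sign for jasmonate biosynthesis genes (-0.10, adjusted p = 3.46e-04), with the call held. Calls were made for 2334 of 21535 genes, 1106 higher and 1228 lower, and 667 and 678 of these differed at least 2-fold. Of the 2334, 2007 were well above background on every array compared and 2 on none, and the slide block gave 2045 calls. Other scalings gave 426 higher and 1461 lower (spike-in scaling) and 580 higher and 298 lower (normexp).

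At day 12, RBCS1A (2.33 ± 0.32), TIP1;2 (2.99 ± 0.26) and FRO8 (3.72 ± 0.23) fell less in acid plants. HSP70-4 (-3.60 ± 0.43), LHY (-4.89 ± 0.37) and RD20 (-2.75 ± 0.24) rose less. Alternatives moved folds over 1.5 times, with quantile normalization for FRO8 (3.12), HSP70-4 (-2.65) and RD20 (-1.67) and with normexp for FRO8 (2.30) and LHY (-3.31). Photosynthesis genes had a median of 0.90 (scan days 0.58 and 1.11, slide block 0.79, spike-in scaling 2.75), adjusted p = 8.47e-04. They numbered 33, with 21 positive, 0 negative and 12 not passing. Of 36 ABA and dehydration response genes, 1 was positive, 17 negative and 18 did not pass. Their median was -1.03 (scan days -0.92 and -1.2, slide block -1.08, -1.0 over the 29 measured), adjusted p = 0.0277. For iron homeostasis genes, 0 of 15 were positive and 10 negative, median -1.53 (scan days -2.30 and -1.31, slide block -1.74, -0.35 over the 8 measured; adjusted p = 0.0308). Both the low signal of the water plants at day 12 and the flower markers of the acid plants at day 0 enter these differences. Some list calls ended with quantile normalization for ABA (-0.15), with normexp for ABA (-0.69), with no filter for ABA (-1.03) and iron (-1.53) and with the strict filter for iron (-0.35). Single arrays also mattered, with calls ending without water replicate 1 of day 12 for ABA (-0.97) and iron (-1.42). With spike-in scaling the median changed sign for ABA genes (0.82, adjusted p = 6.19e-04) and iron genes (0.32, adjusted p = 1.38e-06), with the call held.

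In all, 13011 of 21535 genes passed, 6013 of them higher and 6998 lower, with 3506 and 3986 at least 2-fold apart. Of these, 9698 were well above background on every array compared and 54 on none, and 10941 were called with the slide block. The calls were 16684 higher and 370 lower with spike-in scaling, 2558 higher and 7043 lower with normexp and 6821 higher and 4526 lower with quantile normalization.

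Water plants at day 0 were compared with untreated plants, which were 9 days younger, so this comparison includes plant age. The threonine aldolase gene THA1 (AT1G08630) was 256-fold higher in water plants (log2 8.00 ± 0.33 SE, n = 3) and BCAT-2 207-fold (7.69 ± 0.19). PDF1.2A was at least 36.8-fold higher, and ORA59 (AT1G06160), which regulates it, was higher by 4.03 ± 0.37. The senescence regulator genes ORE1 (AT5G39610) (3.77 ± 0.19) and NAP (AT1G69490) (3.22 ± 0.22) were higher. CYP79F1 (-4.13 ± 0.48) and BAT5 (-2.59 ± 0.30) of aliphatic glucosinolate synthesis were lower. Folds moved over 1.5 times without water replicate 2 of day 0 for CYP79F1 (-3.54). Normexp moved ORA59 (3.01), THA1 (6.25) and, below its bound, PDF1.2A (log2 3.18).

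Of 8 jasmonate and ethylene ERF-branch genes, 8 were higher, 0 lower and 0 did not pass. Their median was 4.69 (scan days 5.26 and 4.32, slide block 4.40, normexp 2.71, strict filter 3.96, 4.29 at bounds), adjusted p = 2.88e-05. 16 of 20 jasmonate signalling and MYC-branch genes were higher, 0 lower and 4 did not pass. Their median was 1.18 (scan days 1.34 and 1.09, slide block 0.98), adjusted p = 0.00189. For salicylic acid defence genes, 11 of 15 were higher and 0 lower, median 2.34 (scan days 2.79 and 1.71, slide block 2.13, normexp 1.29; adjusted p = 0.00706). Senescence genes had 8 of 15 higher and 1 lower, median 0.59 (scan days 0.70 and 0.54, slide block 0.99; adjusted p = 0.0106). Anthocyanin and flavonoid genes had 0 of 14 higher and 13 lower, median -1.91 (scan days -1.32 and -1.92, slide block -1.79, normexp -0.80, -1.34 at bounds; adjusted p = 8.75e-04). Aliphatic glucosinolate genes had 0 of 10 higher and 8 lower, median -2.28 (scan days -2.23 and -2.31, slide block -1.83; adjusted p = 0.00201). Photosynthesis genes had 0 of 33 higher and 18 lower, median -0.48 (scan days -0.45 and -0.54, slide block -0.51; adjusted p = 0.00283). Flower and pollen markers did not pass beside these lists, with 5 of 11 higher and 0 lower (median 1.24, 0.00 at bounds, adjusted p = 0.160). Salicylic acid genes moved over 1.5 times without untreated replicate 2 (1.55) or 3 (3.07).

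Calls of lists ended with the strict filter for salicylic acid (0.51) and aliphatic glucosinolate (-2.59). The test called 12379 of 21535 genes (5967 higher, 6412 lower), of which 1930 and 2747 differed at least 2-fold. Of the 12379, 11140 were well above background on every array compared and 62 on none, and the slide block gave 10778 calls. Spike-in scaling gave 2437 higher and 8458 lower calls.

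Across the 14 comparisons 4 lists never passed. Medians of the 7 glyoxylate cycle genes lay between -0.62 and 0.95, with a lowest adjusted p of 0.0509, in water against untreated plants, where 5 were higher and 2 lower. The 18 histone acetylation enzyme genes had medians of -0.16 to 0.20 (lowest adjusted p = 0.11). For 12 circadian clock genes the range was -0.66 to 1.65 (lowest adjusted p = 0.0667), and for 6 root marker genes -1.41 to 0.35 (lowest adjusted p = 0.180).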

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

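The tests of the scaling, organelle transcripts, labelling, a second flower list, single acid arrays and rapid wound genes were chosen after values they rest on had been seen; the drought course, clock and split tests address results already seen but were set before their own values. A tested difference between the drought responses of acid and water plants drew attention to these results. It includes the day 0 difference between them. At day 6 it covered 1269 genes, with medians of 0.53 for jasmonate signalling and -1.53 for flower and pollen markers (-1.48 over the 3 measured in all 4 groups), and among named genes BCAT-2 (1.99), BT1 (2.67) and LTP3 (-3.42). At day 9 it covered 2334 genes, with medians of 0.16 for jasmonate biosynthesis, 0.62 for jasmonate signalling and -1.22 for anthocyanin genes (-1.15 over the 9 measured), and ADH1 (-1.34), CHS (-3.01), GDPD2 (5.79), JAZ1 (3.04), JAZ7 (5.29), LTP3 (-6.13) and OPR3 (2.15), with CHS at -2.34 without water replicate 2 of day 9. At day 12 it covered 13011 genes, with medians of -1.03 for ABA (-1.0 over the 29 measured), 0.90 for photosynthesis and -1.53 for iron genes (-0.35 over the 8 measured), and FRO8 (3.72), HSP70-4 (-3.60), LHY (-4.89), RBCS1A (2.33), RD20 (-2.75) and TIP1;2 (2.99).

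Each interaction had 100 regroupings of its 12 arrays, the real one included. At day 6, 3 gave as many calls (real 1269, highest other 5024), and 1 did at day 9 (2334 and 2211). At day 12, 2 did (13011 and 13056), all shares under 0.05. The largest others exchange all labels of 1 day and keep the acid effect, so the interaction is not tested alone. Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05, and in each only 1 split, the real one, reached its count. Real and highest other counts were 2436 and 1, 4509 and 0, 4477 and 514 and 15208 and 84 for acid against water plants by day, 10373 and 1, 12733 and 2 and 18613 and 14 for drought in water plants, 10511 and 2, 13724 and 1 and 17429 and 3 in acid plants, and 12379 and 53 for water against untreated plants.

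Most genes differed between acid and water plants at day 12. A single shift of all genes, as another scaling would give, left at least 69.4% of genes called at any size up to 4 log2 units (64.8% to 67.5% with 1 of 6 arrays left out), which argues against scaling as the whole cause of the count. It does not settle how many genes were higher and how many lower, which follows from the scaling used. A lower share of nuclear messenger RNA in water plants would have raised organelle transcripts there; their median difference of -0.83 (chloroplast -0.65, n = 60; mitochondria -0.99, n = 59) lies within the shift of 2.07 from scaling, so this cannot be told apart. A drought response further along in water plants would have placed genes that rose by day 9 in acid plants below those that fell; the difference of 0.18 (0.14 to 0.21 with 1 of 12 arrays left out) was a poor bound because members went both ways (715 higher and 1088 lower, 867 and 1464). Weaker labelling of whole samples would have lowered the added control RNA as well, if that was added before labelling, which the files do not state. The unscaled log2 signal of this RNA was 10.53 ± 0.02 (SD, n = 3) in water and 10.12 ± 0.04 in acid plants, at least 0.35 higher on each water array. Part of this gap is not particular to day 12, since the means were also 10.32 and 10.04 at day 0. Within water plants the signal was not lower at day 12 than at day 0, which argues against weaker labelling. Lower RNA quality of the water plants at day 12 stays open, as the files give no RNA integrity values, and so does a biological difference in drought damage between pretreatments, which was not tested.

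Flower and pollen markers were higher in acid plants at day 0. A second list of 14 flower genes, none of them in another list, had a median of 1.61 at bounds with 12 higher. Of the 14, 13 were above background in all acid samples at day 0 and 3 in all water samples. As entry required signal in some group, the list was partly selected for this and cannot decide. More flower tissue in the acid samples stays a candidate explanation. With 1 acid array left out, the median of the first list was at least 1.68, which argues against a single array as the cause. Whether acid plants flowered earlier or the harvest differed was not tested.

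Many jasmonate genes were higher in acid plants at days 6 and 9. Rapid wound and touch genes, of which 22 of 23 were above background in all water samples at day 0 and none is in another list, had medians of 1.11 at day 6 and 3.25 at day 9 (0.80 at day 0), so a wound or touch response at harvest may contribute. A different time of day would have moved morning and evening clock genes apart; they differed by 0.58 at day 6 and 0.14 at day 9, but evening genes alone ranged from -0.41 to 0.33 and -0.79 to 0.76, so this cannot be told apart. An effect of the acid on jasmonate signalling stays open and untested.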

How the results depend on the processing

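Spike-in scaling, the scan day block and the model without water plants at day 12 were chosen after the data were seen. For counts that moved by over 1.5 times the cause was not tested. Normexp gave 724, 2668 and 1857 calls for acid against water plants at days 0, 6 and 9, 8177 for water plants at day 9, 5826 and 8538 for acid plants at days 6 and 9, 303 and 878 for the interactions at days 6 and 9, and 7652 for water against untreated plants. The slide block gave 705 and 956 for acid against water plants at days 0 and 6. With only the arrays compared there were 1158 and 7090 in those comparisons and 2744 in the interaction at day 6. Spike-in scaling gave 2356 and 2300 for acid against water plants at days 6 and 9 and 235 for the interaction at day 6, which had 2169 without the water plants at day 12. All other counts lay within 1.5 times.

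Leaving out 1 array gave 928 to 2466, 2223 to 3833, 2891 to 4505 and 14306 to 14844 calls for acid against water plants at days 0, 6, 9 and 12, 8741 to 9772, 11590 to 12238 and 18204 to 18403 for drought in water plants, 9149 to 9846, 12579 to 13198 and 16802 to 17025 in acid plants, 603 to 1430, 1634 to 2585 and 12214 to 13002 for the interactions, and 10647 to 11900 for water against untreated plants.

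Replicate numbers pair no samples: correlations of deviations between equal numbers were -0.196 to 0.278, and no comparison had all pairs over 0.1. The replicate block gave 2351 calls at day 0 and 1137 for the interaction at day 6, moved no count by over 1.5 times and ended 1 list call, that of ERF-branch genes in acid against water plants at day 6 (adjusted p = 0.0531).

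Of 84 list calls, 36 ended with the strict filter, which tests fewer members, 7 with quantile normalization, 7 with normexp, 4 with no filter, 5 with the slide block, 2 with the scan day block and 6 with spike-in scaling. 3 reversed with spike-in scaling, jasmonate biosynthesis in the interaction at day 9 (-0.10), and ABA (0.82) and iron (0.32) genes in the interaction at day 12, with their calls held, as the scaling shifts all genes there. Of named genes NCED3 reversed likewise in acid against water plants at day 12 (0.39). The flower list call of day 0 had adjusted p = 8.58e-08 to 0.0337 over 19 alternatives apart from the estimated correlation. Of 126 named gene calls 123 held under each alternative testing them, but mainly genes that held were named. The strict filter tested 95, the model without water plants at day 12 102. Fold changes of named genes moved by over 1.5 times for 46 calls with normexp (all closer to 0), 24 with spike-in scaling, 5 with the slide block, 7 with quantile normalization, 4 with the mean of the probes and 1 with the series matrix values. Medians of called lists moved as far for 24 calls with normexp, 20 with the strict filter, 15 with spike-in scaling, 4 with quantile normalization, 4 with the slide block, 2 with no filter, and 1 each with the mean of the probes and the series matrix values. The reasons were not tested. Genes near background have bounds or wide errors, which limits day 12 in water plants most.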

Other observations

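Transcripts of the organelle genomes were not part of the lists set before the data were examined. Among 60 chloroplast genome transcripts the median difference from day 0 was -0.35 (1 higher, 32 lower) at day 9 and -1.25 (11 higher, 44 lower) at day 12 in water plants, and -0.03 (5 higher, 15 lower) and -1.91 (0 higher, 55 lower) in acid plants. The 59 mitochondrial genome transcripts had medians of 1.2 (42 higher, 9 lower) at day 12 in water plants and 0.18 (19 higher, 19 lower) in acid plants, and the interaction at day 12 was -1.03 (1 higher, 42 lower). Spike-in scaling shifts all genes by -1.78 in water plants at day 12, which is larger than their rise.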
